A study of Mus musculus with 2 samples.

How the data were processed

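Total RNA from the small intestine of C57BL/6 mice, aged 6 to 8 weeks, was compared between conventional chow (Conv) and a food antigen-free diet that supplies amino acids in place of protein (FAF) and was kept up for as many as 5 generations, per the labels. The labels mention both specific-pathogen-free and germ-free mice and do not say which of these gave the RNA. RNA was extracted with Trizol and labelled with the Agilent Quick Amp kit, per the labels' protocols. It was hybridised to 2 Agilent whole mouse genome 4x44K two-colour arrays. On 1 array the Conv RNA carried Cy3 and the FAF RNA Cy5, and on the other the dyes were exchanged. The labels give both arrays the same pair of RNA codes, so the arrays are a technical dye swap and the design holds 1 RNA sample per diet. Whether a sample came from 1 mouse or from a pool is not given in the sources used here.

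The deposited scanner files hold spot intensity on a linear scale for each dye, with local background, from Agilent Feature Extraction 11.5.1.1, per the file headers. They also hold a log10 ratio of Cy5 over Cy3, which the same software corrected for background and dye and, per the file headers, smoothed over intensity, and a p-value for that ratio from the software's error model. Quality flags of each spot, deposited in the same files, mark spots well above background, outliers and saturation. The deposited value table of the series equals the log10 ratio of the scanner files, matched by feature number, to within 5.0e-08, with a median of 0 in each column and no turning for the dye swap. Its direction is therefore Cy5 over Cy3 on both arrays, and nothing about its scale or centring stayed open.

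Ratios were computed from the mean spot intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalised by loess on its own, with control spots at weight 0. The log2 ratio of each array was then turned to FAF over Conv, by the dyes in the labels, and the 2 arrays were averaged, so that a dye effect cancels. Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged. No spot was saturated. A probe was measured when it was well above background in the channel of at least 1 diet on both arrays, which held for 25440 of 41174 probes. A gene was represented by its probe of highest mean intensity, giving 17162 genes. RefSeq names of assembly GRCm38.p6 were found for 27668 probes through their accession, and the other 13506 keep the name in the array file. Probe positions are those of the array files, in mouse build mm9, and the annotation of that build was not used here. Where a gene was not well above background in one diet on both arrays, its fold is a lower bound, taken after loess and quantile scaling of the intensities against the higher of its own signal and the lowest signal that was well above background.

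With 1 RNA sample per diet there is no test between diets and no p-value. A rule of size was used instead: a gene passed when its mean ratio was at least 2-fold and both arrays gave at least 1.5-fold the same way. The ± beside a log2 ratio is the distance of either array from their mean, which measures dye and hybridisation error and leaves out the spread between mice. As a measure of the same error, the rule was also applied to ratios that were not turned for the dye swap. Of each of 41 gene lists, the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on intensity in 10 bins. A list with a percentile under 2.5, or as far out at the upper end, was taken to stand apart, as a description of these 2 RNA samples. The lists, the rule of size, the alternatives and the rule for naming genes were fixed before the data were examined. That last rule takes, among genes that pass, the 12 highest and 12 lowest that have a proper symbol and are well above background in both diets. It adds up to 4 per direction with the largest bound and, from each list, up to 4 members that pass or otherwise 2 of largest absolute ratio, and each gene of the series' title. Some genes that the rule picks are withheld for evaluation, and their values are left out. Genes named outside the rule are marked as chosen after their values were seen.

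The steps were tested on simulated data with the real intensities and dye trend of the FAF against Conv comparison. In these data 200 of 25440 probes were changed, 50 per fold size, besides a list of 15 probes shifted by 0.5 in log2. Noise was drawn with the same spread at every spot, an SD of 0.114 in log2 taken from the difference between the arrays. Unchanged probes could thus hardly reach the 2-fold limit, and their count says little about false calls in the real data. The rule called 0 of the other 25225 probes, which were unchanged. It called 14.0% of those changed 2-fold, 72.0% of those changed 3-fold and 78.0% of those changed 4-fold, in the right direction. Among probes brighter than the median, 100% of the 4-fold changes were called, against 63.3% among dimmer ones, because the offset shrinks the ratios of dim probes. A first bound set for this test, on the share of 4-fold changes called among all probes, was narrowly missed, and it was replaced by a bound on the brighter probes. Ratios of dim genes are therefore understated. Per the file headers, the software's log ratios of the spiked control RNAs followed their known ratios with slopes of 0.880 and 0.894 on the 2 arrays, so those ratios too were somewhat compressed.

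Between 60.9% and 64.3% of the spots outside the controls were well above background in each channel. The number of arrays limits the precision of every value. Both arrays lay on 1 slide and were scanned in 1 session, per the file headers, so no slide or scan separates them. Alternatives covered no background correction, an offset of 10, the software's own log ratio, the deposited value table, median centring, both other filters on dim probes, the mean over a gene's probes, each array alone, other fold limits and the software's p-value.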

Results

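Gene expression in the small intestine was measured in mice on conventional chow (Conv) and in mice on a food antigen-free amino acid diet (FAF), with 1 RNA sample per diet on 2 dye-swapped arrays. The comparison asks which transcripts of the intestine differ between these diets. It does not separate the replacement of protein by amino acids from any other difference between chow and the FAF diet. The series' title concerns helper T cells that are activated by food protein and die, and the production of IL-10. All values are log2 ratios of FAF over Conv, with the distance of either array from their mean after the ± sign. There were no replicate mice to set beside these ratios, so each one describes the 2 RNA samples. Across the 17162 genes measured, the ratios of the 2 arrays had a Pearson correlation of 0.90 and a Spearman correlation of 0.81, as a description, since genes are not independent replicates.

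By the rule of size, 263 genes were higher in FAF and 151 were lower. The same rule called 0 genes when the ratios were not turned for the dye swap. Among genes with a proper symbol, the largest increase was that of Fbp1, fructose-1,6-bisphosphatase of gluconeogenesis, at 3.51 ± 0.11, or 11.4-fold. The largest decrease was that of Ceacam10, at -3.48 ± 0.06, or 11.2-fold lower in FAF. A probe for an immunoglobulin light chain, named only by its accession, stood higher still at 3.81. The Fbp1 probe lies on chromosome 13 at 62966175 to 62966234, and that of Ceacam10 spans positions 25566203 to 25569495 of chromosome 7, both in build mm9.

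**Figure D1:**
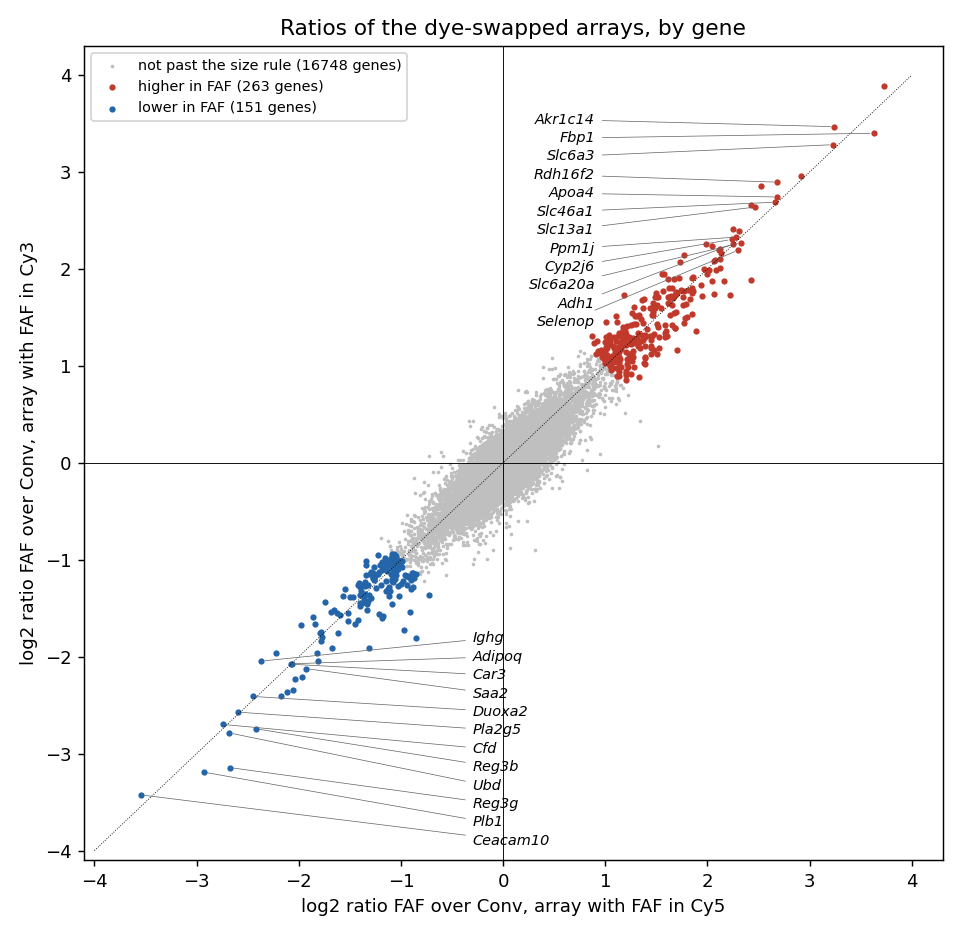
Each point is 1 of 17162 genes, with its log2 ratio of FAF over Conv on the array with FAF in Cy5 (x axis) and on the array with FAF in Cy3 (y axis); red and blue points are the 263 higher and 151 lower genes, the dotted line marks equal ratios, and the 12 highest and 12 lowest genes chosen by the naming rule are labelled. The labelled genes lie close to the dotted line, from Ceacam10 at a mean of -3.48 to Fbp1 at 3.51, and unlabelled points among the called ones include probes named by accession, up to 3.81.

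After Fbp1, the highest genes with a symbol were Akr1c14, a hydroxysteroid dehydrogenase, at 3.35 ± 0.11 and Slc6a3, the dopamine transporter, at 3.25 ± 0.03. Rdh16f2, of the retinol dehydrogenase family, stood at 2.79 ± 0.11, and Apoa4, an apolipoprotein of chylomicrons, at 2.71 ± 0.03. Nutrient transporters followed, with the folate transporter Slc46a1 at 2.68 ± 0.01, the sulfate transporter Slc13a1 at 2.55 ± 0.09 and the proline transporter Slc6a20a at 2.30 ± 0.03. Ppm1j, a protein phosphatase, had a ratio of 2.31 ± 0.02. Cyp2j6, a cytochrome P450, had 2.27 ± 0.03, the alcohol dehydrogenase Adh1 2.25 ± 0.01 and the selenium carrier Selenop 2.25 ± 0.05. Among 7 higher genes that were not well above background in Conv, the largest bounds were at least 5.09-fold for an immunoglobulin kappa variable segment, 3.03-fold for the channel gene Mcoln3, 2.5-fold for Gkn2 and 2.44-fold for Tff1.

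After Ceacam10, the lowest genes with a symbol were Plb1, a phospholipase of the brush border, at -3.06 ± 0.13 and the antimicrobial lectin Reg3g at -2.91 ± 0.23. Reg3b, a lectin of the same family, had -2.58 ± 0.16. Ubd, a ubiquitin-like protein induced by interferon gamma, stood at -2.73 ± 0.05. The secreted phospholipase Pla2g5 had -2.58 ± 0.01, and Duoxa2, the maturation factor of the oxidase Duox2, had -2.43 ± 0.02. The acute-phase gene Saa2 stood at -2.03 ± 0.10 and the immunoglobulin heavy chain Ighg at -2.21 ± 0.16. The fat tissue genes Cfd, Adipoq and Car3 had ratios of -2.72 ± 0.02, -2.08 ± 0.00 and -2.07 ± 0.00. Plb1 and Car3 had other measured probes with smaller decreases, at -0.32 and -0.55. Another probe named for the immunoglobulin gamma heavy chain stood at -0.94. Probes for the constant region of gamma 1 stood at 0.07 and -0.05, those of gamma 2C at -0.33 and -0.57, and that of Ighg3 at 0.24. These immunoglobulin probes were singled out after their values were seen. Fmr1nb alone among the lower genes was not well above background in FAF, with a bound of at least 1.87-fold. Families of near-identical genes, among them Reg3, Saa, Cyp2b, Cyp3a, Ugt2b, the defensins and the immunoglobulins, can share signal between probes, so the ratio of a single member is uncertain.

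Genes of digestion and absorption were higher in FAF as groups. Of 15 measured genes of carbohydrate digestion and sugar transport, 11 passed as higher and 0 as lower, and the median was 1.17 (percentile 100). They included Fbp1, the glucose-6-phosphatase G6pc at 1.70 ± 0.02, sucrase-isomaltase Sis at 1.70 ± 0.07 and lactase Lct at 1.62 ± 0.26. Of 17 genes of fat absorption and chylomicron assembly, 8 were higher and 0 lower, with a median of 0.82 (percentile 100). Examples besides Apoa4 were the fatty acid binding protein Fabp1 at 2.02 ± 0.14, the triglyceride-forming enzyme Dgat2 at 1.88 ± 0.05 and the fatty acid transporter Cd36 at 1.78 ± 0.11. Brush border peptidases and peptide transport had 1 of 14 genes higher, the peptidase Mme at 1.26 ± 0.05, and a median of 0.49 (percentile 99.99). Amino acid transporters had 2 of 17 higher, Slc6a20a and Slc7a15 at 1.21 ± 0.06, and a median of 0.38 (percentile 100). In this list 13 genes were above 0 and 4 below, from Slc1a1 at -0.58 to Slc43a1 at -0.37, singled out after their values were seen. Of 15 vitamin A genes 4 were higher, with a median of 0.50 (percentile 100), among them Aldh1a1 at 1.90 ± 0.16, the carotene-cleaving Bco1 at 1.57 ± 0.03 and the retinol binding protein Rbp2 at 1.53 ± 0.15. Markers of smooth muscle moved the other way on these samples, with a median of -0.52 over 11 genes (percentile 0) and 0 past the rule, as in Des at -0.74 ± 0.16 and Synm at -0.76 ± 0.06.

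Xenobiotic metabolism and fatty acid oxidation genes were higher. Of 24 xenobiotic metabolism genes, 13 were higher and 0 lower, with a median of 1.12 (percentile 100). Cyp3a25 had 2.07 ± 0.01, Cyp2b10 1.97 ± 0.03 and the glucuronosyltransferase Ugt2b5 1.95 ± 0.19. Fatty acid oxidation and PPAR alpha targets had 3 of 21 genes higher and a median of 0.51 (percentile 100), with the kinase Pdk4 at 2.08 ± 0.01, the transcription factor Creb3l3 at 1.34 ± 0.08 and Acot1 at 1.1 ± 0.08. Fatty acid synthesis went lower, with a median of -0.36 over 13 genes (percentile 0.09). In that list the desaturases Scd1 and Scd2 were lower at -1.39 ± 0.21 and -1.37 ± 0.05, while their regulator Srebf1 was higher at 1.23 ± 0.01. Cholesterol synthesis and uptake had a median of -0.20 over 21 genes (percentile 1.11) and 0 genes past the rule, with Sqle at -0.85 ± 0.14, and did not stand apart under 2 of the alternatives. The amino acid response and serine synthesis list had 3 of 19 genes lower and 0 higher, with a median of -0.50 (percentile 0). These were asparagine synthetase Asns at -1.18 ± 0.04, the serine synthesis enzyme Phgdh at -1.17 ± 0.09 and Nupr1 at -1.18 ± 0.16, and another Phgdh probe stood at -0.77, short of the rule. The list was mixed, with 13 genes below 0 and 6 above. Those above included Trib3 at 0.92 and Ddit3 at 0.48, singled out after their values were seen. NRF2 targets did not stand apart, with a median of -0.04 over 10 genes (percentile 37.3), Gsr lower at -1.32 ± 0.06 and Gclm higher at 1.03. Aryl hydrocarbon receptor targets had a median of -0.06 over 4 measured genes (percentile 30.7), with Cyp1b1 at -0.43 ± 0.20 and Tiparp at 0.32 ± 0.02.

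**Figure D2:**
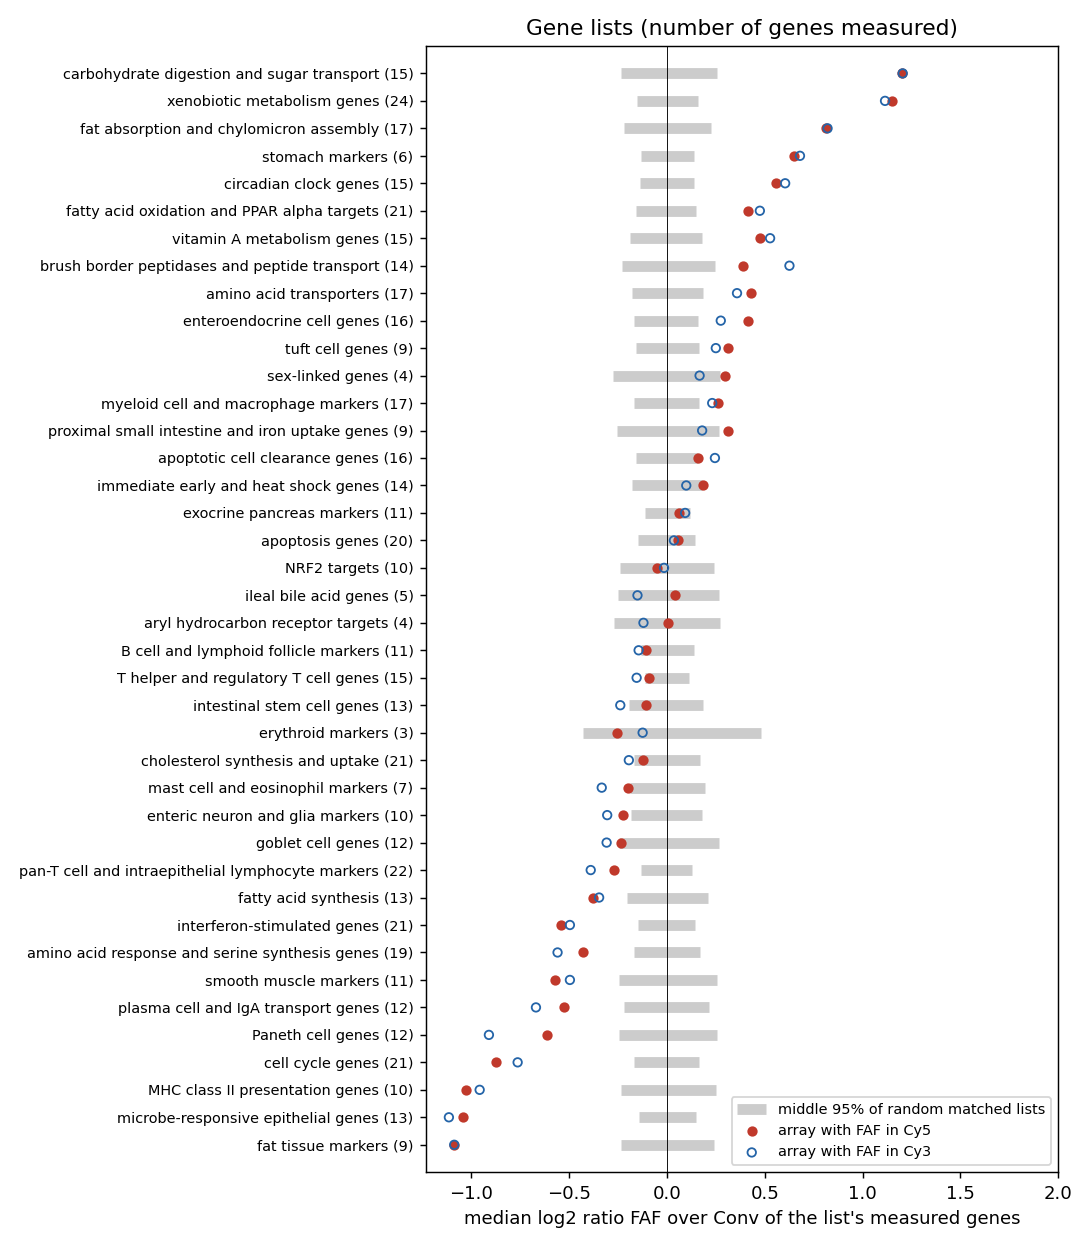
Filled red and open blue points give the median log2 ratio of FAF over Conv of each list's measured genes on the array with FAF in Cy5 and on the array with FAF in Cy3, with the number of genes in brackets; grey bars span the middle of 10000 random lists of the same size and intensity, leaving out 2.5% at either end. Sugar transport, xenobiotic and fat absorption genes lie far to the right of their bars, and fat tissue, microbe-responsive and MHC class II genes far to the left.

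Genes by which the epithelium responds to microbes were lower in FAF. Of 13 measured, 7 were lower and 1 higher, with a median of -1.08 (percentile 0). Besides Reg3g, Reg3b, Pla2g5, Duoxa2 and Saa2, the lower ones were Saa1 at -1.78 ± 0.01 and the chemokine Ccl28 at -1.08 ± 0.03, and the higher one was Reg3a, another lectin of the family, at 1.81 ± 0.04. Duox2, whose maturation needs Duoxa2, had 0.32 ± 0.03. Saa1, Ccl28, Reg3a and Duox2 were singled out after their values were seen. The labels do not say whether the mice were specific-pathogen-free or germ-free, so no value here separates the diet from a difference in microbes. Of 10 MHC class II presentation genes 4 were lower, with a median of -0.95 (percentile 0), namely H2-DMb1 at -1.55 ± 0.11, H2-DMa at -1.38 ± 0.02, H2-Aa at -1.25 ± 0.09 and the invariant chain Cd74 at -1.15 ± 0.04. In that MHC class II list 7 genes were below 0 and 3 above. Those above were Ctss at 0.45, Ifi30 at 0.26 and H2-Oa at 0.10, singled out after their values were seen. Of 21 interferon-stimulated genes 6 were lower and 0 higher, with a median of -0.49 (percentile 0). They included the nucleic acid sensor Zbp1 at -1.89 ± 0.07, Isg15 at -1.42 ± 0.12, Oasl2 at -1.22 ± 0.10 and Usp18 at -1.21 ± 0.08.

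**Figure D3:**
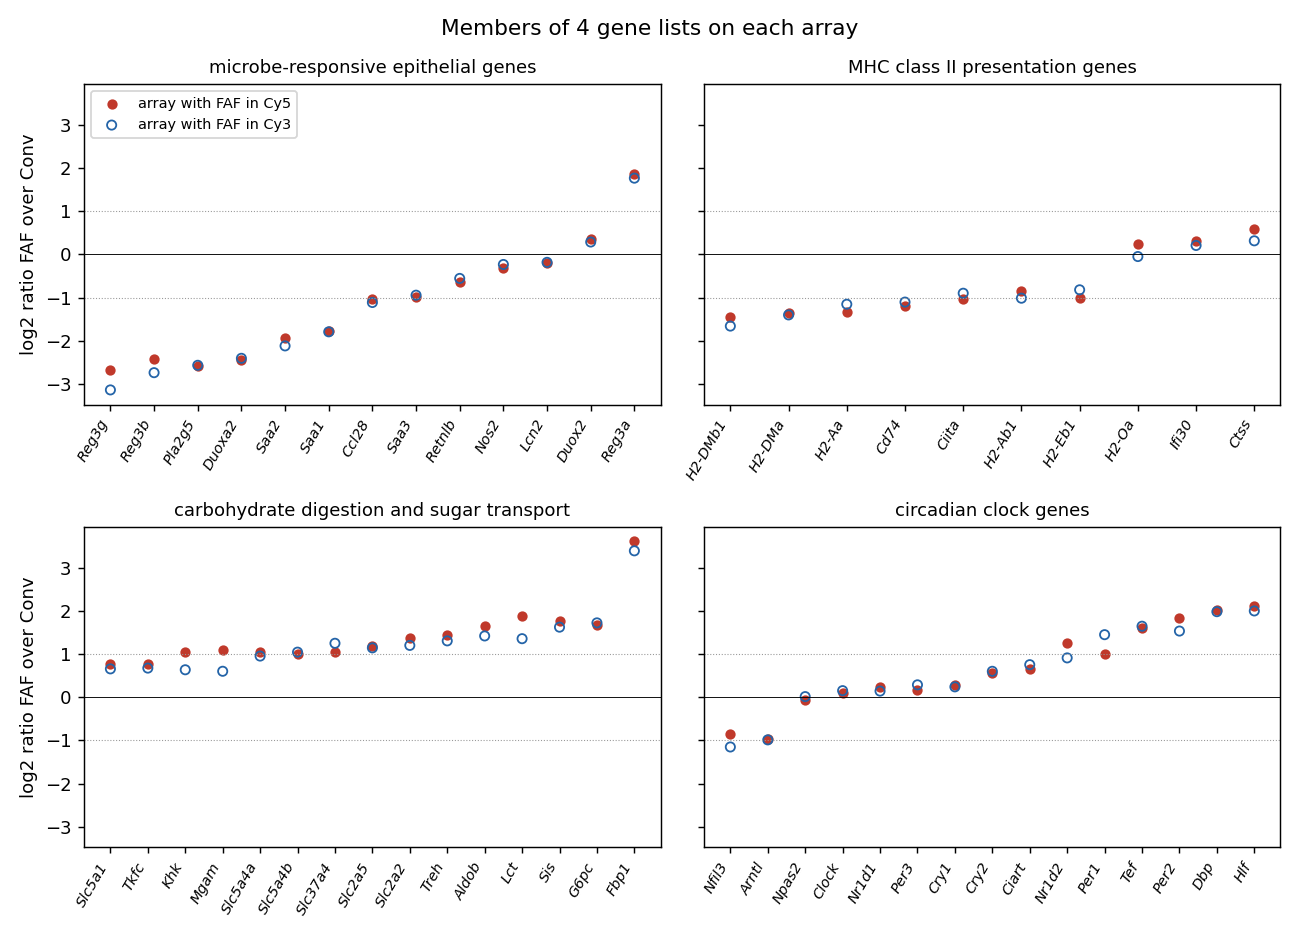
Points give the log2 ratio of FAF over Conv (y axis) of each measured member of 4 lists, filled red for the array with FAF in Cy5 and open blue for the array with FAF in Cy3; dotted lines mark a ratio of 2-fold either way. Reg3a, at 1.81, lies above the upper dotted line in the microbe-responsive list, while Reg3g lies at the bottom, and Hlf and Dbp lead the clock genes.

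Cell cycle and Paneth cell genes were lower. Cell cycle genes had 5 of 21 lower and 0 higher and a median of -0.78 (percentile 0), with Cdc20 at -1.1 ± 0.12, Plk1 at -1.05 ± 0.13 and Ccnb1 at -1.05 ± 0.11, which had another probe at -0.82. Paneth cell genes, of the antimicrobial cells at the crypt base, had 4 of 12 lower and a median of -0.65 (percentile 0), with the pentraxin Mptx1 at -1.77 ± 0.02 and the defensin-processing protease Mmp7 at -1.02 ± 0.12. Defa20 had -1.33 ± 0.48, with a wide gap between the arrays. Intestinal stem cell genes did not stand apart, with a median of -0.15 over 13 genes (percentile 5.45), although they did on the array with FAF in Cy3 alone, and with Smoc2 at -0.59 ± 0.03 and Olfm4 at -0.56 ± 0.13. Goblet cell genes had 2 of 12 lower, Spink4 at -1.23 ± 0.03 and Agr2 at -1.05 ± 0.02, and a median of -0.32 (percentile 0.54), which did not stand apart on the array with FAF in Cy5 alone. Enteroendocrine genes had 2 of 16 higher, neurotensin Nts at 1.41 ± 0.07 and Gip at 1.02 ± 0.02, and a median of 0.33 (percentile 99.95). Tuft cell genes had a median of 0.32 over 9 genes (percentile 99.94) and 0 past the rule, with Rgs13 at 0.69 ± 0.06 and Sh2d6 at 0.44 ± 0.06.

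Of the genes in the series' title, Ikzf2, which encodes Helios, had a ratio of 0.30 ± 0.03 and did not pass, and its other measured probe stood at 0.00. Foxp3, Il10 and Cd4 were not well above background on both arrays in either diet, so whole-tissue RNA gave no ratio for them. T helper and regulatory T cell genes had a median of -0.12 over 15 genes (percentile 2.05) and 0 past the rule, with Ifng, not well above background in FAF, at least 1.59-fold lower on its brighter probe and at -0.34 on the other, and this list did not stand apart under 6 of the alternatives. Pan-T cell and intraepithelial lymphocyte markers had 2 of 22 lower, Cd8b1 at -1.33 ± 0.08 and Cd5 at -1.05 ± 0.01, and a median of -0.33 (percentile 0). Plasma cell and IgA transport genes had 1 of 12 lower, Fkbp11 at -1.07 ± 0.03, and a median of -0.58 (percentile 0). B cell and lymphoid follicle markers did not stand apart, at a median of -0.08 over 11 genes (percentile 11.4), with Cd79b at -0.83 ± 0.10 and Fcrla at -0.49 ± 0.08.

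Myeloid markers had a median of 0.24 over 17 genes (percentile 99.7), while their 1 member past the rule, the endotoxin co-receptor Cd14, was lower at -1.08 ± 0.06. Apoptotic cell clearance genes had 2 of 16 higher, the engulfment receptor Mertk at 1.58 ± 0.05 and the cholesterol exporter Abca1 at 1.07 ± 0.08, and a median of 0.18 (percentile 98.5), which did not stand apart on the array with FAF in Cy5 alone. Apoptosis genes did not stand apart, with a median of 0.04 over 20 genes (percentile 72.7), Bcl2l11 at 0.49 ± 0.26 and Pmaip1 at 0.48 ± 0.04. Mast cell and eosinophil markers had a median of -0.27 over 7 genes (percentile 0.48) and 0 past the rule, with Mcpt1 at -0.78 ± 0.06 and Prg2 at 0.73 ± 0.06.

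Circadian clock genes differed between the samples. Of 15 measured, 6 were higher and 1 lower, with a median of 0.58 (percentile 100). The higher ones included the transcription factors Hlf at 2.07 ± 0.06, Dbp at 2.0 ± 0.02 and Tef at 1.63 ± 0.02, and the clock repressor Per2 at 1.69 ± 0.16, and the lower one was Nfil3, singled out after its value was seen, at -1.0 ± 0.15. Other measured probes of Per2 and Tef reached down to 0.03 and 0.28. The labels give no hour of collection.

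Markers of neighbouring tissues and of sampling were set beside these groups. Fat tissue markers had 5 of 9 genes lower and 1 higher and a median of -1.13 (percentile 0), with Lpl at -1.27 ± 0.19, and -0.72 on its other probe, besides Cfd, Adipoq and Car3. Stomach markers had 2 of 6 higher, Gkn2 and Tff1, and a median of 0.66 (percentile 100). Both genes were well above background in FAF only, and the list did not stand apart when genes had to be well above background in both diets. Exocrine pancreas markers had 1 of 11 higher, Sycn at 1.28 ± 0.01, and a median of 0.07 (percentile 87.2). Enteric neuron and glia markers had a median of -0.29 over 10 genes (percentile 0.18), with Vip at -0.60 ± 0.07 and Elavl4 at -0.36 ± 0.02, and erythroid markers -0.19 over 3 genes (percentile 18.2), with Hbb-bt at -0.34 ± 0.06 and Alas2 at -0.19 ± 0.07. Ileal bile acid genes had a median of -0.06 over 5 genes (percentile 29.9), with Nr1h4 at -0.58 ± 0.13 and Slc51b at -0.58 ± 0.03. Fabp6 and Fgf15 of that list were not well above background in either diet. Which segment of the small intestine was taken is not given in the sources used here. Proximal intestine and iron uptake genes had 2 of 9 higher, Lct and Adh6a at 1.06 ± 0.03 (0.70 on its other probe), and a median of 0.22 (percentile 94.8). Immediate early and heat shock genes had a median of 0.15 over 14 genes (percentile 94.9), with Fos at 0.88 ± 0.13 and Jun at 0.53 ± 0.03. Sex-linked genes had a median of 0.25 over 4 genes (percentile 96.5), with the Y-linked Eif2s3y at 0.35 ± 0.20 and Kdm5d at 0.27 ± 0.08. Xist was not well above background in either diet.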

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

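All alternatives here were planned before the data were examined. The software's own log ratio and the deposited value table gave the same counts, 487 genes higher and 350 lower, which shared 260 and 151 with the main 263 and 151. A mean of at least 1.5-fold with both arrays the same way, and no limit for each array, gave 775 and 616 genes. A mean of at least 4-fold gave 31 and 18. Median centring in place of loess gave 183 higher and 82 lower, left a correlation of 0.16 between the arrays and called 99 genes when the ratios were not turned, since the dye trend over intensity then stays in each array and cancels only in their mean. Under the other alternatives, no background correction, an offset of 10, other filters on dim probes, the mean over a gene's probes and the software's p-value, the counts ran from 230 to 320 higher and from 139 to 201 lower. The arrays taken alone gave 286 and 268 higher, and 144 and 172 lower. No gene called in the main setting changed sign, and no gene taken by the naming rule and no list that stood apart did, under any alternative on the values. Between 26 and 31 lists stood apart, against 29 in the main setting. The T helper list was lost under 6 alternatives, the cholesterol list under 2, and the stomach, goblet cell and clearance lists under 1 each. Lists that stood apart only under an alternative were proximal intestine under 2, and B cell, sex-linked, ileal, immediate early and stem cell genes under 1 each. Signal over background limits the ratios of dim genes, which the offset shrinks, and 1 RNA sample per diet limits all of them. No paired analysis was possible because the result comes from no test.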

Other observations

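The genes and groups of this paragraph and the next were chosen after the values were seen. All 77 measured ribosomal protein genes had a ratio below 0, with a median of -0.36 (percentile 0 among random lists matched on intensity), and the median stayed between -0.41 and -0.27 under each alternative, although 1 gene each was not below 0 without the filter on dim probes and on the array with FAF in Cy5 alone. Replication histone genes had 7 of 31 lower and a median of -0.61, with H2ac23 at -1.35 and H1f5 at -1.31. The 3 measured gasdermin C genes, Gsdmc, Gsdmc2 and Gsdmc3, were lower at -1.36, -1.27 and -1.34. All 6 measured Cyp3a genes and 4 of 6 Ugt2b genes were higher, with medians of 1.71 and 1.61, and 6 of 12 carboxylesterase genes were higher, with a median of 0.87. Other single genes past the rule were the glutathione peroxidase Gpx2 at -1.82 ± 0.15, the mucin-like Dmbt1 at -1.73 ± 0.14, complement C3 at -1.53 ± 0.02, the kinase Sgk1 at 2.16 ± 0.04 and the cytokine Il15 at 1.32 ± 0.05.

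Probes for immunoglobulin transcripts went both ways. Of 149 measured, 6 were higher and 29 lower, or 23.5% called, against 1.82% of all other measured probes, with means from -2.29 to 3.81. Probes named Ptprz1, Prm1 and Krtap19-1, genes of glia, sperm and hair, had ratios of -1.23, -1.77 and -1.80 at mean log2 intensities of 17.1, 15.7 and 14.1, and no other value here bears on their identity.

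In the next 3 paragraphs, the tests of the stem cell, myeloid and interferon gamma lists were chosen after the values were seen. Absorptive genes were higher and fat tissue markers lower in FAF. A larger share of epithelium in the FAF RNA would raise general epithelial genes alike, and the median of 18 of them, among them Epcam, Cdh1 and Vil1, was -0.062, against 1.08 for the sugar and fat absorption genes, which argues against it as the source of the latter, although smooth muscle and enteric neuron markers were lower (-0.52 and -0.29), as that share would make them. A larger share of villus against crypt cannot be told apart from a change within the cells: the cell cycle and Paneth cell medians of -0.78 and -0.65 go with it, while the stem cell median was -0.15 (-0.10 and -0.24 on the 2 arrays) with 4 of 13 members above 0. Less attached fat tissue in the FAF RNA cannot be told apart from a change within the tissue, since a second list of 10 measured fat genes had a median of 0.078 with members on both sides, from Cyp2e1 at -0.71 and Plin4 at -0.70 to Aqp7 at 0.69. An effect of the diet on the absorptive cells stays open and was not tested.

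MHC class II genes were lower in FAF. Fewer antigen-presenting cells would lower myeloid and B cell markers as well, and their medians were 0.24 and -0.08, against -0.95 for the MHC class II list. This argues against a loss of the cells that the myeloid list marks. For B cells the median decides little, since the offset shrinks the ratios of dim genes. Of the 11 B cell markers measured, 8 were below 0, with Cd79b at -0.83, and 3 were above. Of 18 B cell markers listed, 7 were not well above background, and no list of dendritic cell genes was tested. Less transcription induced by interferon gamma may be a source, as a hypothesis: 12 measured genes of that response had a median of -0.37 (percentile 0.08), among them Tap1 at -0.99, Socs1 at -0.90 and Psmb8 at -0.88, while Gbp3 and Gbp4 stood at 0.08 and 0.16. A first version of that list also held Psmb9, Igtp, Irgm2 and Ubd, already seen as lower, and these 4 were taken out before the value given here. A family of 15 interferon-induced GTPases, chosen after the values were seen, shares members with that list. It had a median of -0.20 (percentile 1.42), with 9 genes below 0 and a range from -1.81 to 0.84. Ifng itself was not well above background in FAF. No value here separates interferon gamma from other interferons.

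Clock genes differed between the diets. If the samples were collected at different clock phases, other genes in phase with Dbp and Per2 would be higher too, and the 4 of them set down before their values were seen had a median of 0.88, from Wee1 at 0.25 to Bhlhe40 at 1.28. A different clock phase at collection is thus consistent with these values, while of the genes of the opposite phase, named after their values were seen, Nfil3 and Arntl stood at -1.0 and -0.98, and Npas2 and Clock at -0.02 and 0.13. Whether such a phase came from the hour of collection or from feeding on the FAF diet was not tested, since each diet has 1 RNA sample. Genes of digestion and drug metabolism that follow the clock could share this source, and no value here separates it from the diet.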
